A study of Mus musculus and Homo sapiens with 14 samples.

How the data were processed

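RNA sequencing counts of 14 libraries were used: 8 from the mouse macrophage line RAW264.7 in 4 groups and 6 from the human colon cancer line HCT116 in 3 groups, with 2 libraries in each group. RNA had been isolated with a column kit and libraries made for Illumina sequencing, per the labels' protocols. The submitters' processing notes name cutadapt 3.4, STAR, HTSeq, SAMtools and DESeq2 and the genome builds mm10 and GRCh38, without saying what each was used for. The library kit, the strand setting and the annotation release are not stated.

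The RAW264.7 files hold raw counts per gene as deposited, in the layout of htseq-count, with whole numbers for 43432 mouse genes. The last 5 rows, reads assigned to no gene, held 9.20% to 9.63% of each library's total and were left out of library sizes and tests. The HCT116 files hold estimated counts per gene as deposited, for 60504 human genes, with 8.46% to 8.87% of values not whole, and what assigned fractions of reads is not stated. They were rounded to whole numbers for the tests. Both kinds of file were unnormalized, and 0 columns of values were left unused.

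Mouse identifiers were given symbols and mm10 coordinates from the GENCODE annotation in the reference, which matched 42462 of 43432. No table or annotation of human genes was used here, so HCT116 genes are given by identifier, their gene lists were not tested, and the planned comparisons of the response between the cell lines were not made. Groups were taken from the labels. The numbers of the replicates were treated as labels only.

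Counts were tested in R 4.3.3 with edgeR 4.0.16: genes passing filterByExpr at its default settings, TMM scaling, and the quasi-likelihood F test, with all groups of a cell line in a single fit and no further covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and 13340 mouse and 16472 human genes were tested. The standard error of a log2 fold change is its size divided by the square root of F. All 7 comparisons, 4 in RAW264.7 and 3 in HCT116, each among 2 libraries against 2, used this test. CPM are scaled by the TMM factors. Fold changes against a group with 0 counts were bounded with a floor of 3 counts over the group, and ratios against 1 to 3 counts were given with an exact 95% counting interval.

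A set of 31 gene lists was fixed before the data were examined, and 553 of 554 entries matched a symbol, since 1 was unmatched. The 30 lists with at least 2 tested members in RAW264.7 were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with the rotation test fry. Of these, 13 passed for LPS against vehicle, 15 at 32 µM, 15 at 10 µM and 14 between the doses at the preset correlation, and 4, 3, 0 and 2 with an estimated correlation. Genes were named by a rule fixed beforehand. It took 14 genes of the NRF2 pathway and inflammation whether called or not, and up to 4 called members of each list with the largest changes. It added the 5 largest increases and 5 largest decreases among called genes with a mean of at least 50 counts in the higher group, no overlap of libraries between the groups and no predicted-gene name. The text names a part of these.

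The procedure was tested on simulated data made from the libraries' means and spread, with 200 genes changed by known folds, 50 per fold. For 32 µM with LPS against LPS it recovered 39 of 50 genes changed 1.25-fold, 38 changed 1.5-fold, 43 changed 2-fold and 48 changed 4-fold, and called 10 of 12974 unchanged genes, out of 13199 tested. For HCT116 at 32 µM it recovered 27, 44, 41 and 49 of 50, and called 15 of 15985 unchanged genes, out of 16210 tested. Of 100 random lists, 8 had an unadjusted camera p under 0.05 in each of these simulations. Genes were drawn independently there too, so this does not check camera on lists whose genes are correlated. To see what shared control libraries give with no effect, groups were simulated 20 times from the control libraries' means. Each gene was drawn independently, so deviations common to many genes of a library are absent. The simulations may therefore understate what shared libraries give.

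The alternatives tried were RLE factors, library totals only, DESeq2 1.42.0, no count filter, a mean of at least 50 counts, only the groups compared, a replicate block, and leaving out each library in turn. In RAW264.7, DESeq2 gave no adjusted p for 1811 genes at 32 µM, 2069 at 10 µM and 1811 between the doses. A GC content and length correction, leaving out RNA genes without a poly(A) tail (3870 genes, of which 76 were tested), and removing both outlying HCT116 libraries were added after seeing the data. With a library left out, its group's lone library is assumed to vary like the other groups.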

Results

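RNA from 14 libraries of 2 established cell lines was sequenced to measure gene expression after treatment with a macrolide glycoside of cyanobacterial origin, named auriside in the sample titles. RAW264.7, a mouse macrophage line, received vehicle (0.5% DMSO), bacterial lipopolysaccharide (LPS, 1 µg/mL, an agonist of Toll-like receptor 4) with vehicle, or LPS with the compound at 10 or 32 µM. The compound preceded LPS by 1 h, and RNA was collected after 12 h. HCT116, a human colon cancer line, received vehicle or the compound at 10 or 32 µM without LPS. Each of the 7 groups held 2 libraries numbered as biological replicates, so n = 2 in each group throughout. Library totals were 35842014 to 48097144 gene counts in RAW264.7 and 62413892 to 74843116 in HCT116. Levels are given as CPM (counts scaled to library size) ± SD, and log2 fold changes ± standard error (SE). Intervals and floors on counts cover counting error only, and p-values of single genes rest on the spread between the numbered libraries. Camera's p-values for lists set the genes of a list against all other genes. They depend on the correlation between genes, preset or estimated. The first principal component of the RAW264.7 libraries held 83.1% of the variance and parted the vehicle libraries from the 6 LPS-treated libraries. The next component held 5.31% and ordered the LPS-treated groups by dose.

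LPS against vehicle gave the inflammatory response on which the compound was tested. Il1b, the gene for interleukin-1β (ENSMUSG00000027398, mm10 chromosome 2, 129364570 to 129371139), stood at 1.42 ± 0.22 CPM in vehicle and at 1672 ± 46.4 CPM with LPS, a log2 fold change of 10.19 ± 0.10. Nos2, the gene for inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), went from 0.0495 ± 0.070 to 52.9 ± 13.4 CPM. Il1a had 0 counts in both vehicle libraries and 313 ± 5.53 CPM with LPS, at least 9194-fold higher against a floor of 3 counts over the group. Il6 had 2 counts in vehicle, which puts its ratio at 599 with a 95% counting interval of 165 to 4951. Tnf rose by a log2 fold change of 5.94 ± 0.07 and Ptgs2, which encodes cyclooxygenase-2, by 5.67 ± 0.09.

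Of the 25 tested genes of the proinflammatory cytokine and effector list, 24 rose, none fell and 1 did not pass, both over all genes and when adjusted over the list alone. All 29 tested interferon-stimulated genes rose, over all genes and adjusted over the list alone, with a median log2 fold change of 3.71. Among them, Rsad2 rose by 6.24 ± 0.09, Ifit3 by 5.77 ± 0.13 and Gbp2 by 5.76 ± 0.09, and Ifnb1, the gene for interferon-β, was at least 101-fold higher than its vehicle level of 0 counts. All 22 tested genes of the NF-κB pathway and its feedback rose, with the same count adjusted over the list alone, including Cd40 (6.16 ± 0.07), Tnfaip3 (5.36 ± 0.06), Traf1 (5.22 ± 0.06) and Nfkbiz (4.08 ± 0.08). The 3 lists passed camera's competitive test against all other genes (adjusted p = 1.5e-78, 9.8e-83 and 6.0e-63 for cytokines, interferon-stimulated genes and NF-κB). All 3 passed with an estimated correlation as well (adjusted p = 0.0178, 0.0158 and 0.0226). Socs3 (6.77 ± 0.07) and Il10 (4.60 ± 0.11), brakes on cytokine signalling, rose within the list of alternative activation and anti-inflammatory genes, of which 8 of 11 tested rose, 2 fell and 1 did not pass (the same counts adjusted over the list alone; adjusted p = 6.8e-09, and 0.0226 with an estimated correlation).

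Genes of the NRF2 antioxidant pathway went both ways after LPS. Of 25 tested NRF2 targets, 13 rose, 10 fell and 2 did not pass, and adjusted over the list alone 14 rose and 10 fell. The list did not pass camera's test (adjusted p = 0.0787, and 0.588 with an estimated correlation), though it did without LPS replicate 1 (0.0203) or 2 (0.0209) and with RNA without a poly(A) tail left out (0.0398). Slc7a11, the cystine transporter, rose by 3.53 ± 0.07, Srxn1 by 2.16 ± 0.04 and Hmox1 by 0.72 ± 0.05. Gclc, the catalytic subunit of glutamate-cysteine ligase, fell by 0.53 on the log2 scale (SE 0.04), and Nfe2l2, which encodes NRF2, fell by 0.44 (SE 0.04). Keap1, the gene for the repressor of NRF2, stood at 87.0 ± 1.6 CPM in vehicle and 85.4 ± 0.72 CPM with LPS (log2 fold change -0.03 ± 0.04, adjusted p = 0.58), and with scaling by library totals only it was called lower (-0.26, adjusted p = 1.9e-05). Nqo1 passed narrowly at low levels (0.52 ± 0.22, adjusted p = 0.040), and its call ended with library totals only (0.29, adjusted p = 0.24), with the GC content and length correction (0.32, adjusted p = 0.19), with only the 2 groups fitted (adjusted p = 0.082) and with DESeq2 (adjusted p = 0.0698). It also ended without any of the 4 vehicle or LPS libraries (adjusted p = 0.15, 0.055, 0.11 and 0.088 without vehicle replicates 1 and 2 and LPS replicates 1 and 2).

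Mitotic genes fell together with LPS: 20 of 22 tested were lower, none was higher and 2 did not pass, with the same counts adjusted over the list alone and with Ccnb2 at -1.40 ± 0.06 and Bub1b at -1.21 ± 0.05 (adjusted p = 4.7e-06, and 0.215 with an estimated correlation). Of 20 genes of ribosome biogenesis and MYC targets 18 rose, none fell and 2 did not pass, with the same counts adjusted over the list alone (adjusted p = 2.9e-06, and 0.263 with an estimated correlation). Myc itself rose by 6.74 ± 0.08 and Odc1, the first enzyme of polyamine synthesis, by 3.53 ± 0.05. Tlr4, which encodes the LPS receptor, fell by 2.06 on the log2 scale (SE 0.05), while Cd14, its co-receptor, rose by 1.49 ± 0.05. The decreases with the largest sizes included S1pr1 (-5.74 ± 0.20), Alox5 (-5.42 ± 0.14) and Cxcr4 (-5.37 ± 0.15), genes for a sphingosine-1-phosphate receptor, 5-lipoxygenase and a chemokine receptor. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 9251 of 13340 tested genes, 4571 higher and 4680 lower, of which 1126 and 1348 changed at least 2-fold (797 and 828 with a mean of at least 50 counts required). Scaling by library totals only moved the median over all genes from -0.02 to -0.25 and gave 2775 higher and 6973 lower, so directions of small changes after LPS are relative to the scaling used.

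The question the series title sets for the compound is its effect on the KEAP1/NRF2 pathway and on inflammation. At 32 µM with LPS against LPS alone, antioxidant genes under NRF2 rose. Nqo1, which encodes a quinone reductase (ENSMUSG00000003849, mm10 chromosome 8, 107388225 to 107403206), went from 1.38 ± 0.015 to 6.48 ± 0.55 CPM, a 4.67-fold increase (log2 fold change 2.22 ± 0.16, adjusted p = 3.2e-08). Hmox1, the gene for heme oxygenase-1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), went from 783 ± 38 to 1901 ± 77 CPM (1.28 ± 0.05, adjusted p = 6.4e-11). Gclm, the modifier subunit of glutamate-cysteine ligase, rose by 1.03 ± 0.05 and Osgin1 by 1.11 ± 0.09. Smaller increases were measured for Srxn1 (0.56 ± 0.04), Gclc (0.47 ± 0.04), Slc7a11 (0.39 ± 0.06), Txnrd1 (0.31 ± 0.04) and Nfe2l2 itself (0.29 ± 0.04). Of the 25 tested NRF2 targets 20 rose, none fell and 5 did not pass, and adjusted over the list alone 22 rose and none fell. The list passed camera's test (adjusted p = 8.0e-34), also with an estimated correlation (adjusted p = 0.0413).

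**Figure D1:**
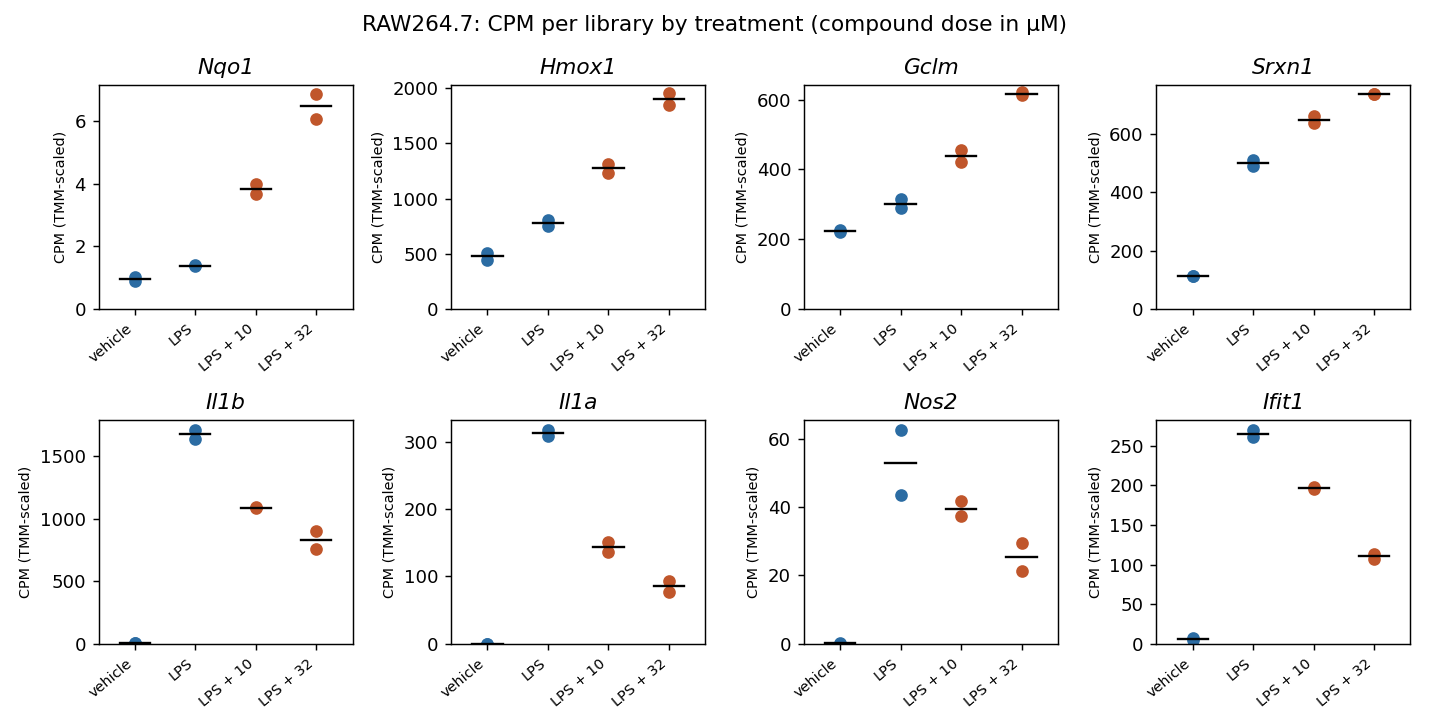
CPM values (TMM-scaled, linear axes from 0) of 8 genes in each RAW264.7 library by treatment, with 2 libraries per group as points and the group mean as a line. Nqo1 stands at 1.38 CPM with LPS alone and at 6.48 CPM with LPS and 32 µM, while Il1a stands at 313 and 85.2 CPM.

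Regulators of NRF2 and enzymes that supply NADPH followed in part. Bach1, a transcriptional repressor that competes with NRF2, rose by 0.55 ± 0.05, and Sqstm1, whose protein p62 binds KEAP1, by 0.35 ± 0.03. Keap1 was lower (-0.17 ± 0.04, adjusted p = 0.0070), a call that ended without 32 µM replicate 2 (adjusted p = 0.0525). In the list of KEAP1 and NRF2 regulators 4 of 10 rose, 2 fell and 4 did not pass (5 and 2 adjusted over the list alone; 1 fell without 32 µM replicate 2; adjusted p = 0.014, and 0.139 with an estimated correlation). Taldo1 (0.51 ± 0.04), Me1 (0.41 ± 0.04) and Pgd (0.27 ± 0.04) were the increases with the largest sizes among 9 NADPH and pentose phosphate enzymes, of which 4 rose, none fell and 5 did not pass. Without LPS replicate 2, 1 of them fell. Adjusted over that list alone, 4 rose and 2 fell (adjusted p = 0.0062, and 0.134 with an estimated correlation).

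Inflammatory genes fell at 32 µM, though not all. Il1a went from 313 ± 5.53 to 85.2 ± 12 CPM, 3.67-fold lower (log2 fold change -1.88 ± 0.07, adjusted p = 6.0e-11). Csf2 (-1.56 ± 0.34), Ccl7 (-1.11 ± 0.05), Nos2 (-1.06 ± 0.14), Il1b (-1.01 ± 0.06), Il6 (-0.71 ± 0.12) and Tnf (-0.50 ± 0.05) were lower as well. Ptgs2 stood at 2318 ± 227 CPM with LPS and 2425 ± 120 CPM with the compound (0.06 ± 0.07, adjusted p = 0.56). Of the 25 tested cytokine and effector genes 20 fell, none rose and 5 did not pass, and adjusted over the list alone 21 fell. The list passed camera's test (adjusted p = 5.6e-24), but not with an estimated correlation (adjusted p = 0.0751). Of the NF-κB pathway genes 10 of 22 fell, 2 rose and 10 did not pass (12 and 2 adjusted over the list alone), with Traf1 at -0.38 ± 0.04, Tnfaip3 at -0.37 ± 0.04 and Nfkb1 at -0.35 ± 0.04. The 2 higher genes became 0 to 1 without an LPS or a 32 µM library. That list had an adjusted p of 0.0019, and of 0.406 with an estimated correlation. Il1a overlaps Gm14023 and Il1b overlaps Il1bos in the annotation, as Gclm overlaps Gm6061 and Sqstm1 overlaps Mrnip. These overlaps are between gene bodies, and overlap of exons was not computed. Reads counted as ambiguous, 1.70% to 1.82% of each RAW264.7 library, were left out. The strand setting of the counting is not stated, so whether such neighbours changed these counts cannot be told.

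Interferon-stimulated genes fell the most as a group. Ifit1 (ENSMUSG00000034459, mm10 chromosome 19, 34640871 to 34650009) went to 110 ± 3.9 CPM at 32 µM, 2.41-fold lower than with LPS alone (-1.27 ± 0.05, adjusted p = 6.0e-11). Mx2 (-1.36 ± 0.07) and Zbp1 (-1.25 ± 0.05), antiviral effectors, and Ifnb1 (-2.02 ± 0.23) were lower too. Of 29 tested genes 28 fell, none rose and 1 did not pass, and adjusted over the list alone all 29 fell. The median was -0.89 (adjusted p = 1.8e-114), and the list passed with an estimated correlation (adjusted p = 0.0413).

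**Figure D2:**
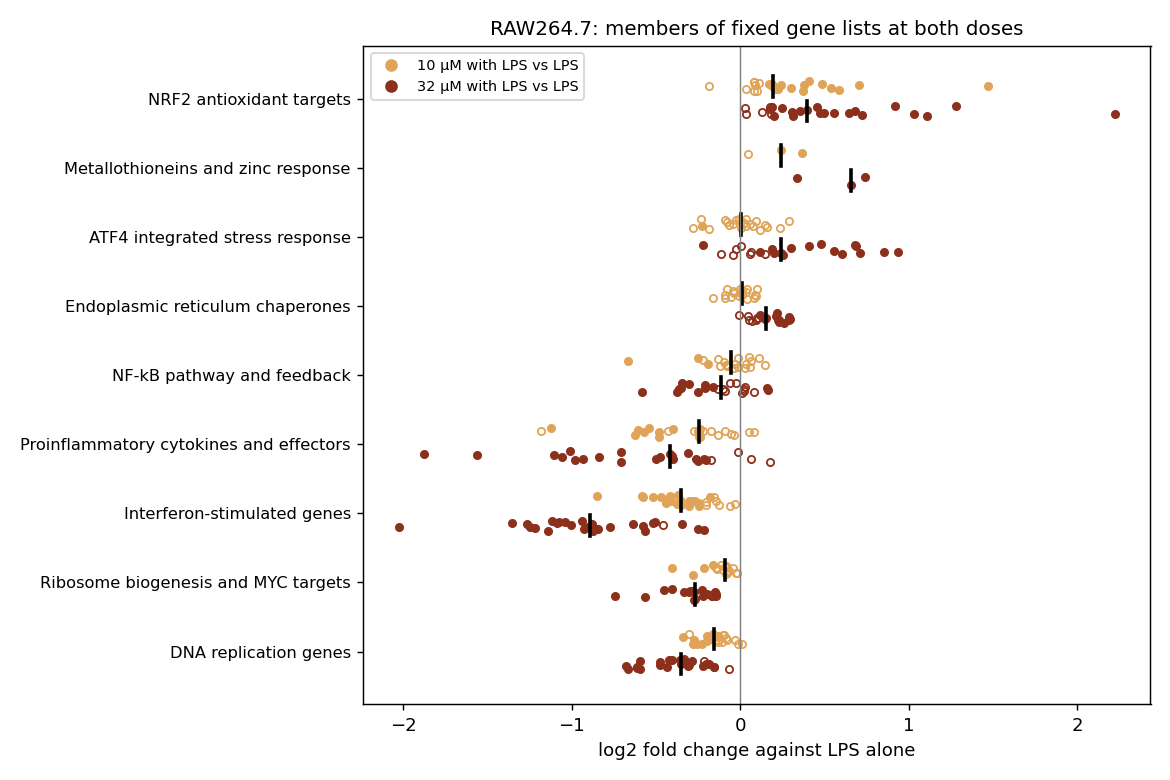
Log2 fold changes against LPS alone of the members of 9 gene lists in RAW264.7 at 10 and 32 µM (filled points passed the test, open points did not, black bars are list medians). The interferon-stimulated genes have medians of -0.35 at 10 µM and -0.89 at 32 µM, and the NRF2 targets 0.20 and 0.39.

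Stress, metal and growth genes also changed at 32 µM. In the list of ATF4 targets of the integrated stress response 14 of 23 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone, and 9 rose without 32 µM replicate 1. Aldh1l2 (0.93 ± 0.10), Slc6a9 (0.85 ± 0.10), Trib3 (0.71 ± 0.15) and Phgdh (0.69 ± 0.05), genes of one-carbon and amino acid metabolism and a stress pseudokinase, had the increases with the largest sizes (adjusted p = 7.4e-09 for the list, and 0.0413 with an estimated correlation). Endoplasmic reticulum chaperones such as Pdia6 and Manf (both 0.29 ± 0.04) rose in 12 of 19, none fell and 7 did not pass (14 higher adjusted over the list alone; adjusted p = 1.6e-05, and 0.387 with an estimated correlation), and 7 rose without 32 µM replicate 1. All 3 genes of the metallothionein and zinc list rose, over all genes and adjusted over the list alone, with Mt2 at 0.74 ± 0.05 and Mt1 at 0.66 ± 0.05 (adjusted p = 2.3e-08, and 0.0547 with an estimated correlation). DNA replication genes fell in 22 of 25, none rose and 3 did not pass (24 lower adjusted over the list alone), including Cdc6 (-0.68 ± 0.10) and Mcm6 (-0.67 ± 0.05). All 20 genes of ribosome biogenesis and MYC targets fell, over all genes and adjusted over the list alone, including Odc1 (-0.57 ± 0.05) and Cad (-0.45 ± 0.06), and Myc fell by 0.74 on the log2 scale (SE 0.05). Those 2 lists passed camera's test (adjusted p = 5.8e-21 and 4.3e-15), but not with an estimated correlation (adjusted p = 0.102 and 0.112).

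Outside the lists, the increases with the largest sizes at 32 µM included Sstr5, a somatostatin receptor gene (3.04 ± 0.41), Tpm2, the gene for β-tropomyosin (2.97 ± 0.25), Enpp2, which encodes autotaxin (2.05 ± 0.21), and Adh7, an alcohol dehydrogenase gene (1.95 ± 0.08). Tnc (-2.44 ± 0.18) and Thbs1 (-2.06 ± 0.14), genes of matrix proteins, were among the decreases. Rn7sk, a small nuclear RNA gene, was called lower (-2.39 ± 0.58, adjusted p = 0.0066), but its level rested on LPS replicate 2, without which its value was -0.63 (adjusted p = 0.378). In all 3034 of 13340 genes were called, 1433 higher and 1601 lower, of which 71 and 88 changed at least 2-fold. The changes of at least 2-fold numbered 28 higher and 51 lower with a mean of at least 50 counts required, and 37 and 60 with DESeq2. Scaling by library totals only gave 1882 higher and 1217 lower. Without 32 µM replicate 1, 932 were higher and 1137 lower, and without replicate 2, 860 and 1056.

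At 10 µM with LPS against LPS alone, NRF2 targets, cytokines and interferon-stimulated genes moved the same way as at 32 µM, with smaller medians. Nqo1 went from 1.38 ± 0.015 to 3.84 ± 0.22 CPM (1.47 ± 0.17, adjusted p = 8.5e-05), Hmox1 from 783 ± 38 to 1274 ± 56 CPM (0.70 ± 0.05, adjusted p = 2.4e-06), and Osgin1 (0.59 ± 0.09), Gclm (0.54 ± 0.05) and Srxn1 (0.37 ± 0.04) rose. Slc7a11 (0.09 ± 0.06, adjusted p = 0.54) and Keap1 (-0.07 ± 0.04, adjusted p = 0.42) did not pass. Of 25 NRF2 targets 15 rose, none fell and 10 did not pass, with 16 higher adjusted over the list alone (adjusted p = 4.1e-32, and 0.101 with an estimated correlation). Taldo1 (0.27 ± 0.04) and Sqstm1 (0.26 ± 0.03) rose as well.

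Il1a fell to 143 ± 9.5 CPM at 10 µM (-1.12 ± 0.07, adjusted p = 2.1e-07), and Il1b (-0.62 ± 0.06) and Lif (-0.57 ± 0.07) were lower. Of 25 cytokine and effector genes 10 fell, none rose and 15 did not pass, and 19 fell when adjusted over the list alone (adjusted p = 2.0e-27, and 0.107 with an estimated correlation). Il6 (-0.48 ± 0.12, adjusted p = 0.026) lost its call without LPS replicate 1 (adjusted p = 0.115), 10 µM replicate 1 (0.0892) or 10 µM replicate 2 (0.232). Tnf (-0.24 ± 0.05, adjusted p = 0.015) lost its call without 10 µM replicate 2 (adjusted p = 0.193) and with DESeq2 (0.0943). Nos2 (-0.43 ± 0.13, adjusted p = 0.10) did not pass, though it did without LPS replicate 2 (-0.67, adjusted p = 0.00068) and without 32 µM replicate 1 (0.0393) or 2 (0.0330). It also passed with only the 2 groups fitted (0.0495) and with no count filter (8.4e-10). Ptgs2 stood at 2229 ± 160 CPM (-0.06 ± 0.07, adjusted p = 0.76). Of 29 interferon-stimulated genes 21 fell, none rose and 8 did not pass, with 25 lower adjusted over the list alone, including Ifit2 (-0.59 ± 0.06), Mx2 (-0.58 ± 0.06) and Rsad2 (-0.52 ± 0.06). Without 10 µM replicates 1 and 2, 11 and 13 of them fell. Their median was -0.35 (adjusted p = 8.6e-54, and 0.101 with an estimated correlation).

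Mitochondrially encoded genes rose at 10 µM: 8 of 12 tested were higher, none was lower and 4 did not pass (9 higher adjusted over the list alone), including mt-Nd4 (0.39 ± 0.06) and mt-Nd2 (0.32 ± 0.05), genes of respiratory complex I. That list had an adjusted p of 6.7e-12, and of 0.197 with an estimated correlation, and 4 genes were higher without 10 µM replicate 2. The rise was not larger at 32 µM, where 5 rose, none fell and 7 did not pass (6 and 1 adjusted over the list alone), and the median was 0.16 against 0.29 at 10 µM. The list did not pass there (adjusted p = 0.066, and 0.591 with an estimated correlation), though it did with no count filter (0.00398) and without LPS replicate 1 (0.0346), 32 µM replicate 1 (0.0298) or 10 µM replicates 1 (0.0465) and 2 (0.0464). At 32 µM 2 genes rose without LPS replicate 1 and 1 without 32 µM replicate 2, while 1 gene fell without LPS replicate 2 or any vehicle or 10 µM library. DNA replication genes fell in 9 of 25, none rose and 16 did not pass (15 lower adjusted over the list alone; adjusted p = 7.7e-13, and 0.197 with an estimated correlation), with Rrm2 at -0.28 ± 0.05, and only 1 and 3 fell without 10 µM replicates 1 and 2. The changes with the largest sizes included Enpp2 (1.34 ± 0.21), Prl2c2 (1.11 ± 0.13), Thbs1 (-1.12 ± 0.13), Tnc (-0.96 ± 0.15) and Nox1, an NADPH oxidase gene (-0.74 ± 0.07). In all 501 of 13340 genes were called, 207 higher and 294 lower, of which 7 and 7 changed at least 2-fold (6 and 3 with DESeq2, and 7 and 3 with a mean of at least 50 counts required). Leaving out 10 µM replicate 1 left 161 calls, 73 higher and 88 lower, with 3 and 3 at least 2-fold. Leaving out 10 µM replicate 2 left 203, 98 higher and 105 lower, with 5 and 2 at least 2-fold.

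The 2 doses were compared directly to see which changes differed between them. Nqo1 (0.75 ± 0.13), Hmox1 (0.58 ± 0.05), Gclm (0.50 ± 0.05) and Gclc (0.25 ± 0.04) were higher at 32 than at 10 µM, as were 14 of 25 NRF2 targets, with none lower and 11 not passing (15 higher adjusted over the list alone; adjusted p = 2.7e-16, and 0.0928 with an estimated correlation). Il1a (-0.75 ± 0.07), Csf1 (-0.73 ± 0.07) and Il1b (-0.39 ± 0.06) were lower at 32 µM, as were 9 of 25 cytokine and effector genes, with none higher and 16 not passing (10 lower adjusted over the list alone; adjusted p = 1.1e-09, and 0.199 with an estimated correlation). Interferon-stimulated genes were lower in 27 of 29, with none higher and 2 not passing, also adjusted over the list alone, and Zbp1 and Ifit1 were both at -0.84 ± 0.05 (adjusted p = 4.0e-97, and 0.0346 with an estimated correlation).

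ATF4 targets separated the doses. At 10 µM against LPS alone 1 of 23 fell, none rose and 22 did not pass, whereas at 32 against 10 µM 12 rose, none fell and 11 did not pass (15 higher adjusted over the list alone; adjusted p = 6.7e-18, and 0.0278 with an estimated correlation). Trib3 (0.94 ± 0.15), Aldh1l2 (0.82 ± 0.09) and Atf3 (0.65 ± 0.06) were the examples with the largest sizes. Endoplasmic reticulum chaperones were higher in 12 of 19, with none lower and 7 not passing (15 higher adjusted over the list alone; adjusted p = 2.0e-11, and 0.199 with an estimated correlation), including Manf (0.38 ± 0.04) and Sdf2l1 (0.31 ± 0.04), and 4 were higher without 32 µM replicate 1 as without 10 µM replicate 2. Tpm2 went from 0.522 ± 0.093 CPM at 10 µM to 4.17 ± 0.68 CPM at 32 µM, 7.98-fold higher. Mitochondrially encoded genes were lower as a list at 32 than at 10 µM by camera (median -0.14, adjusted p = 0.0129, but 0.506 with an estimated correlation and 0.192 with fry), with 1 of 12 lower, none higher and 11 not passing (4 lower adjusted over the list alone). That list did not pass without 32 µM replicate 1 (0.141) or 10 µM replicate 2 (0.458), where 0 of its genes were lower, while 6 were lower without 10 µM replicate 1 and 3 without either LPS replicate. In all 1161 of 13340 genes were called between the doses, 522 higher at 32 µM and 639 lower, of which 7 and 10 differed at least 2-fold (4 and 4 with a mean of at least 50 counts required). Scaling by library totals only gave 708 higher and 467 lower. The calls numbered 269 higher and 378 lower without 32 µM replicate 1, 250 and 333 without replicate 2, 250 and 314 without 10 µM replicate 1, and 206 and 354 without replicate 2.

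How far the compound acted on genes that LPS had moved was counted over all of them. Of the 1126 genes that LPS raised at least 2-fold, 450 were called lower and 90 higher at 32 µM, and 177 lower and 26 higher at 10 µM. Of the 1348 that LPS lowered at least 2-fold, 248 were called higher and 27 lower at 32 µM, and 29 higher and 5 lower at 10 µM. The LPS libraries enter both comparisons, which alone favours opposite signs: 74.1% of the raised genes lay lower at 32 µM and 72.1% at 10 µM, against 53.6% and 53.3% in 20 simulations with no effect of the compound. When the choice of genes and the comparison used different LPS libraries, the shares were 70.3% and 69.1% at 32 µM and 67.2% and 66.8% at 10 µM. Without 10 µM replicates 1 and 2, 69 and 76 of the raised genes were called lower at 10 µM and 8 and 14 higher. Over the 4571 genes that LPS raised by any fold, 1122 were called lower and 406 higher at 32 µM (64.2% lay lower), and 240 lower and 76 higher at 10 µM (61.2% lay lower).

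Both doses called 188 genes higher and 274 lower, where independent lists of these sizes would share 22.2 and 35.3, and simulated groups with no effect shared at most 2 higher and 1 lower. Over 9002 genes above 8 CPM, the log2 fold changes of the 2 doses had a correlation across genes of 0.80 and a covariance of 0.020, against 0.51 and 0.0023 in the simulations. Without 10 µM replicates 1 and 2, 68 and 93 genes were higher at both doses and 84 and 101 lower. Genes are not independent replicates, and part of the excess may come from the shared LPS libraries. The simulations held no deviations common to many genes of a library, so they set a low mark.

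HCT116 was treated without LPS, which shows the compound's effect in a human tumour line. Its gene identifiers came without names in the files, and no table to name them was at hand, so no gene list was tested there. At 32 µM 278 of 16472 tested genes were called, 165 higher and 113 lower, of which 17 and 6 changed at least 2-fold. DESeq2 gave 153 higher and 194 lower, with 2 and 0 at least 2-fold, and a mean of at least 50 counts left 9 and 3 at least 2-fold. However, DESeq2 gave no adjusted p for 10219 of the 16472 genes, which could therefore not be called. Without 32 µM replicate 2, 10 and 6 changed at least 2-fold. ENSG00000149591 went from 4.53 ± 0.67 CPM in vehicle to 10.6 ± 0.19 CPM at 10 µM and 28.8 ± 2.0 CPM at 32 µM, with log2 fold changes of 1.22 ± 0.09 (adjusted p = 8.9e-07) and 2.67 ± 0.09 (adjusted p = 7.3e-13). ENSG00000163017 had 6 counts in vehicle and reached 1.82 ± 0.36 CPM at 32 µM (5.40 ± 0.43, adjusted p = 4.5e-07). ENSG00000273217 had 131 counts in vehicle and none at either dose, at least 39.0-fold lower at 32 µM and 39.6-fold lower at 10 µM against a floor of 3 counts over the group. That floor covers counting error only, and not errors in how these estimated counts assigned reads to genes. DESeq2 called 0 genes at least 2-fold lower at either dose, so it did not call ENSG00000273217.

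**Figure D3:**
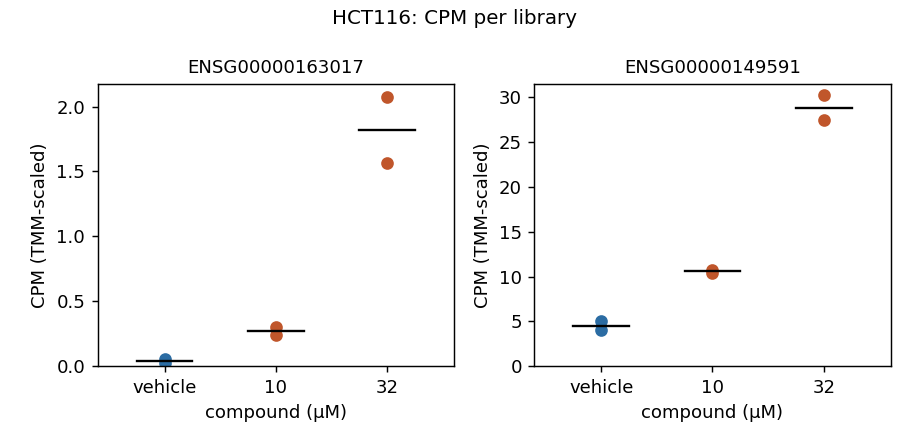
CPM values (TMM-scaled, linear axes from 0) of 2 genes in each HCT116 library by compound dose, with 2 libraries per group as points and the group mean as a line. ENSG00000149591, in the right panel, has means of 4.53 CPM in vehicle, 10.6 CPM at 10 µM and 28.8 CPM at 32 µM.

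At 10 µM 108 genes were called in HCT116, 63 higher and 45 lower, of which 7 and 6 changed at least 2-fold (0 and 0 of 109 and 84 with DESeq2, and 5 and 3 with a mean of at least 50 counts required). DESeq2 gave no adjusted p for 9261 genes here, which could not be called. Those changed at least 2-fold numbered 5 and 3 without vehicle replicate 1, 11 and 4 without vehicle replicate 2, and 12 and 11 without 10 µM replicate 2. With only the 2 groups fitted, 72 were higher and 86 lower. Scaling by library totals only gave 157 higher and 162 lower at 32 µM, and 52 higher and 66 lower at 10 µM. Both doses called 35 genes higher and 4 lower, where independent lists would share 0.63 and 0.31 and simulated groups with no effect shared at most 3 and 4, so the overlap in the lower direction was within the simulated range. The 35 became 13 without vehicle replicate 1 and 16 without 10 µM replicate 1, and the 4 became 2 and 1 there and 14 without 32 µM replicate 2. Over 9947 genes above 8 CPM, the log2 fold changes at the 2 doses had a covariance of 0.0026, against 0.0017 in the simulations, but a correlation of 0.33, below the 0.49 of the simulations. Without vehicle replicates 1 and 2, 91 and 96 genes were higher at 32 µM and 41 and 15 lower. Without 32 µM replicates 1 and 2, 128 and 112 were higher and 33 and 62 lower. At 10 µM, 18 were higher and 6 lower without vehicle replicate 1, 46 and 15 without vehicle replicate 2, and 23 and 8 without 10 µM replicate 1. Leaving out 32 µM replicates 1 and 2 gave 74 and 70 lower at 10 µM.

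Between the doses in HCT116, 887 genes were called, 422 higher at 32 µM and 465 lower, of which 16 and 10 differed at least 2-fold (2 and 0 with DESeq2, and 8 and 4 with a mean of at least 50 counts required). DESeq2 gave no adjusted p for 7665 genes here. The 887 calls exceeded the count of either dose against vehicle. Of the 887, 412 lay below vehicle at 32 µM and above it at 10 µM, 295 lay the other way round, 107 were above vehicle at both doses and 73 below it at both. Between the doses, 295 were higher and 140 lower without 32 µM replicate 1, 73 and 48 without 32 µM replicate 2, and 78 and 48 without 10 µM replicate 1. Those that differed at least 2-fold numbered 11 and 3 without 32 µM replicate 2, and 23 and 21 without 10 µM replicate 2. On the third principal component of HCT116, which held 20.2% of the variance, 32 µM replicate 1 (26.1) and 10 µM replicate 2 (-20.6) lay farthest apart. On the first principal component, which held 23.4% of the variance, 10 µM replicate 1 (27.1) and 32 µM replicate 2 (-22.2) lay farthest apart. With both of these libraries removed 117 genes were called, 72 higher and 45 lower.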

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

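Calls changed direction only after LPS, where 162 were called the other way with library totals only and 23 with the GC content and length correction. None of the genes followed by name was among them. In every setting that gave the gene an adjusted p, 42 of 43 called after LPS and 60 of 63 at 32 µM were called. So were 29 of 42 at 10 µM and 26 of 36 between the RAW264.7 doses. The lists of NRF2 targets, cytokines and interferon-stimulated genes passed camera's test at both doses in all 16 refits, but with an estimated correlation the adjusted p was 0.0751 for cytokines at 32 µM, and 0.101, 0.107 and 0.101 for NRF2 targets, cytokines and interferon-stimulated genes at 10 µM. The planned rotation test (fry) asks whether a list changed, not whether it changed more than other genes. Among the calls that fry did not give were those of cytokines (0.0538), NF-κB genes (0.0677) and mitochondrially encoded genes (0.192) between the doses. Lysosome genes at 32 µM (0.0772) and NF-κB (0.204) and cholesterol genes (0.139) at 10 µM did not pass fry either. NRF2 targets after LPS (0.000243), the actin list (0.00113) and the lipid efflux list (0.0256) at 32 µM passed it. The GC content and length correction, the removal of RNA without a poly(A) tail and the removal of both outlying HCT116 libraries were tried only after seeing the data.

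Deviations of same-numbered libraries correlated only weakly, at -0.0025 to 0.0919 in RAW264.7 and 0.0110 to 0.0513 in HCT116. On the third principal component of RAW264.7, with 2.81% of the variance, replicate 1 lay above replicate 2 in every group. The scores were 16.0 and -15.5 with LPS, 1.54 and -1.52 with vehicle, 12.3 and -8.65 at 32 µM, and 0.553 and -4.72 at 10 µM. A batch shared by the numbers is thus not excluded. A replicate block called 798 genes at 10 µM in RAW264.7 (501 without), 294 genes higher at both doses (188 without) and 2 HCT116 genes lower at both doses (4 without), and by direction, calls at 10 µM in RAW264.7 went from 207 to 345 higher and from 294 to 453 lower, and at 32 µM in HCT116 from 113 to 71 lower. With the block, Nos2 at 10 µM (-0.41, adjusted p = 0.00083), the NRF2 list after LPS (0.0428) and the actin (0.0402) and mitochondrially encoded (0.0419) lists at 32 µM passed. Of the LPS-raised genes, 41 were then higher at 10 µM (26 without). Counting LPS-raised genes of any fold, 4571 instead of 1126, gave 1122 lower and 406 higher at 32 µM, and the share that lay lower fell from 74.1% to 64.2% (from 72.1% to 61.2% at 10 µM). With no count filter, 313 genes were higher at 10 µM in RAW264.7 (207 in the main run), and the genes that changed at least 2-fold also rose in number. In HCT116, library totals gave 9 genes lower at both doses and DESeq2 8, and DESeq2 called 193 genes at 10 µM. With no count filter 560, 552 and 1439 genes were called at 32 µM, at 10 µM and between the doses, and 68 and 34 were higher and lower at both doses. Removing both outlying HCT116 libraries left 117 calls between the doses and 22 and 13 genes higher and lower at both. The cause of these differences between settings was not tested.

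Leaving out each library in turn gave 1916 to 2854 calls at 32 µM, 161 to 664 at 10 µM and 560 to 1523 between the doses in RAW264.7. The LPS-raised genes called lower at 10 µM then numbered 69 to 191, and the genes called at both doses 68 to 255 higher and 84 to 348 lower. In HCT116 the ranges were 111 to 277 at 32 µM, 24 to 143 at 10 µM and 121 to 756 between the doses, with 13 to 33 higher and 1 to 14 lower at both. The lowest values came without 32 µM replicate 2 (1916), 10 µM replicate 1 (161, 69, 68 and 84) and 10 µM replicate 2 (560) in RAW264.7. In HCT116 they came without vehicle replicate 2 (111), vehicle replicate 1 (24 and 13), 32 µM replicate 2 (121) and 10 µM replicate 1 (1). In the simulation of HCT116 at 32 µM, 27 of 50 genes changed by the smallest seeded fold were recovered. The planned comparisons of the response between the cell lines were not run, because HCT116 genes could not be matched to mouse genes.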

Other observations

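All tests of explanations in this part were chosen after the pattern they address was seen. Only for the carry-over test of RNA without a poly(A) tail was the prediction written before the test was run.

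Some cytoskeletal, lysosomal and lipid genes passed the test, mostly in lists that moved both ways. Of 14 tested genes of the actin cytoskeleton under SRF and YAP, 6 rose, 2 fell and 6 did not pass at 32 µM (7 and 3 adjusted over the list alone; 4 fell without LPS replicate 1 and 1 without 32 µM replicate 2), with Cnn2 at 0.97 ± 0.18 and Tpm4 at 0.41 ± 0.05, and the list did not pass camera's test (adjusted p = 0.055), though it did with library totals only (0.0439) and without 32 µM replicate 1 (0.0338) or 10 µM replicate 1 (0.0465) or 2 (0.0464). Of 10 tubulin genes 5 rose, 3 fell and 2 did not pass, with the same counts adjusted over the list alone, including Tubb2a (0.61 ± 0.07) and Tuba1a (0.47 ± 0.05), and that list did not pass either (adjusted p = 0.13, but 0.0268 without LPS replicate 2; 3 rose without LPS replicate 1 or without either 32 µM replicate). Of 27 lysosome and autophagy genes 10 rose, 2 fell and 15 did not pass (14 and 2 adjusted over the list alone), and 5 rose without 32 µM replicate 2, while 1 fell without LPS replicate 2 or any library of a dose. Gpnmb (0.82 ± 0.08) and Tfeb, a transcription factor of lysosomal genes (0.70 ± 0.11), were higher and Npc2 was lower (-0.34 ± 0.05), and the list's adjusted p was 0.0031, but 0.0844 without LPS replicate 1 and 0.573 with an estimated correlation. Of 11 genes of lipid efflux under LXR, 3 rose, 4 fell and 4 did not pass at 32 µM (the same counts adjusted over the list alone; 1 rose without 32 µM replicate 1), and the list did not pass (adjusted p = 0.20). Abca1 (-0.83 ± 0.10) and Fasn (-0.57 ± 0.06), genes of lipid efflux and fatty acid synthesis, were lower at 32 µM and at 10 µM (-0.57 ± 0.10 and -0.40 ± 0.06). Ahrr, the repressor induced by the aryl hydrocarbon receptor, was higher at 32 µM (1.42 ± 0.16), as was Tiparp (0.30 ± 0.06). Tlr4 was 0.70 ± 0.05 higher at 32 µM than with LPS alone.

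Cholesterol genes differed between the doses. At 10 µM 6 of 21 were lower, none was higher and 15 did not pass (9 lower adjusted over the list alone; 2 lower without 10 µM replicate 1), with Insig1 at -0.43 ± 0.06 (for the list, adjusted p = 1.7e-06, and 0.329 with an estimated correlation). At 32 µM 10 rose, 5 fell and 6 did not pass (the same counts adjusted over the list alone), and the list did not pass (adjusted p = 0.18, but 0.0338 without 32 µM replicate 1; 6 rose without LPS replicate 1 and 4 without 32 µM replicate 2, and 3 fell without 32 µM replicate 1). Between the doses 10 were higher at 32 µM, none was lower and 11 did not pass (14 higher adjusted over the list alone; adjusted p = 7.2e-10, and 0.199 with an estimated correlation; 2 higher without 32 µM replicate 2 or 10 µM replicate 1), with Cyp51 at 0.40 ± 0.05. Nfatc1, a transcription factor of osteoclast formation, was lower at 32 than at 10 µM (-0.47 ± 0.04), as were Ltbp1 (-1.21 ± 0.12) and Myc (-0.46 ± 0.05), while Tagln2 was higher (0.37 ± 0.04).

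The interferon-stimulated genes fell more at 32 µM than genes that LPS had raised to a similar degree. Their LPS-raised members, 28 genes, had a median log2 fold change of -0.898, against -0.399 for 10000 random lists of LPS-raised genes matched on the LPS response (95% of lists from -0.664 to -0.194). None was as low, a share of 0.0001, the smallest these lists can give. Random lists ignore correlation between genes, estimated at 0.134 for this list after LPS. Their spread is therefore too narrow, and the share is not a p-value over libraries. The interferon list was also singled out because it fell the most, which favours an extreme rank. Within these limits the medians argue only against an equal weakening of genes with a similar LPS response. Cytokines (-0.413 against -0.547) and NF-κB genes (-0.132 against -0.336) lay at or above their random lists. A single weakening of LPS signalling that reaches these lists unequally cannot be excluded this way. A trend on GC content and length does not account for the fall of the interferon-stimulated genes, whose median was -0.897 after correction. Nor does LPS replicate 2, without which their median was -0.869. A candidate explanation is that the compound lowers interferon signalling apart from other LPS targets, and the lower Ifnb1 transcript leaves open whether less interferon-β or a later step is involved, which was not tested.

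In HCT116 more genes were called between the doses than for either dose against vehicle. With only 32 µM replicate 2 and 10 µM replicate 1 kept at the doses, 1044 genes were called, whereas with only the other 2 dose libraries 117 were, and the mixed choices gave 384 and 410. These 2 libraries were chosen because they lay farthest apart on the first principal component. The counts restate their position and do not show what set them apart. On the third component the other 2 dose libraries lay farthest apart. A difference in handling or growth state and an effect that goes opposite ways at the 2 doses cannot be told apart. The labels give no batch and each dose has 2 libraries. All 39 genes called at both doses against vehicle moved the same way, which the shared vehicle libraries favour.

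Gm42418, a gene singled out after its values were seen, had 128045 counts in LPS replicate 2 and 21837 in LPS replicate 1, a log2 ratio of 2.61, and Rn7sk had 175 and 31 counts (2.49). If RNA without a poly(A) tail had been carried over in general, other such genes should be higher there too. The other 74 tested genes had a median log2 ratio of -0.0765 (bootstrap interval -0.286 to 0.0531), which argues against a carry-over shared by all such genes. Of them, 4, with at most 21 counts there, were at least 2-fold higher. Most of the 74 were small nucleolar RNA genes with low counts, so they say little about long or abundant RNAs. The long and abundant mitochondrial ribosomal RNAs mt-Rnr1 (11525 counts in replicate 1 and 10504 in replicate 2) and mt-Rnr2 (14359 and 11958) were not raised there. They stood at 255 to 519 CPM in every RAW264.7 library, so their steady level does not bear on carry-over. The library kit is not stated, so selection for poly(A) tails is itself an assumption of the test. A carry-over limited to some RNAs stays open, among them Rn7sk and the nuclear ribosomal RNA, whose gene Gm42418 overlaps in the annotation. No biological explanation was tested, as both libraries had the same treatment.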
